A study of Homo sapiens with 8 samples.

How the data were processed

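OVISE cells with wild-type SYK (SYK-WT) or with SYK knocked out (SYK-KO) were profiled by paired-end Illumina sequencing of total RNA, untreated or after EGF at 50 ng/ml for 24 h, with 2 libraries in each of 4 groups. Per the labels' protocols, the knockout used a Cas9 nickase with a pair of guides, puromycin selection and isolation of single-cell clones. Groups and replicate numbers were taken from the sample titles. FPKM values per library and locus were made by the authors with the Cufflinks suite, with TopHat, Cufflinks and Cuffdiff 2.2.1.3 and the build hg19 named in the submitters' processing notes. Parameters and the method of scaling libraries are not given in the sources used here, nor is the strand of the reads. The p-values and q-values of 3 comparisons are those of the authors' deposited table, per the file headers, and only the q-values are printed. A column of values was matched to every library by its title, and the columns that hold a library more than once were equal.

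The table held 27757 loci named by transcript accessions. Symbols were found for 27541 of them (99.2%), 27218 from the RefSeq table and 323 from GENCODE annotation of GRCh38, and 216 had none. GRCh38 was used for symbols, for the GC content and length of transcripts, and for placing the guides, while coordinates of genes are those of the authors' table in hg19. A listed locus can cover several neighbouring genes: 47 of the 183 genes named by rule shared one with another entry. Overlapping and antisense genes are uncertain because strand is not given, as are families with near-identical copies.

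FPKM are not counts, so the quasi-likelihood test that the design had fixed for counts was replaced by the test the design had fixed for FPKM. Loci with at least 1 FPKM in at least 2 libraries were kept, which left 12112, of which 12076 had a symbol, 388 merged several symbols, 180 held a small RNA and 11317 had a coding accession. Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 with a mean-variance trend, 1 mean per group and all 4 groups sharing the spread, with 4 residual degrees of freedom and a prior of 3.87. The contrasts were EGF in SYK-WT cells, EGF in SYK-KO cells, SYK-KO against SYK-WT untreated and with EGF, and the difference between the EGF responses. P-values were two-sided and adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. Tables and plots were made in python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

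The depth was estimated from loci of up to 0.5 FPKM, where values step by the worth of a single fragment. The relative depth of a library is the step at which the most such loci agreed, within 0.01 on the log2 scale. The absolute depth took transcript lengths from GENCODE and 552 loci above 0 in at least 4 libraries, whose depth-scaled values lay within 0.1 of whole multiples of the smallest, which was taken as 1 fragment. It gave a median of 27200000 fragments for SYK-WT replicate 1, with quartiles of 26400000 and 27900000. The estimates were 27200000 and 24900000 fragments for SYK-WT, 26700000 and 27200000 for SYK-KO, 27100000 and 24900000 for SYK-WT EGF, and 23100000 and 26100000 for SYK-KO EGF, in the order of the replicates. These estimates hold only if FPKM were scaled by each library's own fragments. Under another scaling, the step would give the scaling factor and not the depth, and the method is not given. Counts were not recovered for the test.

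The fit was tested on simulated data, in which 200 of 12112 genes were changed by known amounts in the SYK-WT EGF libraries. For EGF in SYK-WT cells it found 74% of 50 genes changed by 0.5 on the log2 scale and 100% of those changed by 1, 2 or 4, with 13 false calls. For the difference of the EGF responses it found 22% at 0.5 and 100% at the larger sizes, with 6 false calls, and for EGF in SYK-KO cells, where nothing was changed, it made 0 calls. The simulated noise was normal and independent between libraries, with an SD per gene shared by all groups. In the data the SYK-WT pair differed more (median 0.149 on the log2 scale, against 0.0608 to 0.0771 in the other groups). The simulated rates may therefore not hold for these data.

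Genes named in the text are, per comparison, the 8 largest rises and 8 largest falls among those past the threshold with a mean of at least 5 FPKM in the higher group and the same direction in every pair of libraries, without small RNAs or merged symbols. For the difference of the responses the limit was 5 in each direction, which left PLAT. SYK, EGFR, ERBB2 and ERBB3 were always named, and up to 4 members with the smallest adjusted p from each described list. MMP1 for the difference of the responses, PLAT for EGF in SYK-KO cells and the single genes named among the other observations were chosen after their values were seen. Values of some genes that the rule names are not reported here.

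The 22 lists held 312 entries. They covered ERK feedback and early genes, ERBB ligands and receptors, the SYK pathway, cell cycle, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, mesenchymal and epithelial genes, matrix proteases and invasion, NF-kappaB targets and cytokines, interferon response, p53 targets, unfolded protein and ATF4 targets, YAP and TEAD targets, FOXO targets, NRF2 targets, genes high in clear cell carcinoma, and markers of fibroblasts, haematopoietic cells, endothelium and mesothelium. Lists were tested against the other genes with camera at a preset correlation of 0.01, and again with an estimated correlation. The design also fixed fry, which asks whether a list changed at all and not whether it changed more than other genes. Its result is given for described lists where it fell on the other side of the threshold from camera at the preset correlation. Adjustment was over the lists of a contrast.

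Genes were also ordered by their hg19 position and grouped into windows of about 100 genes, 117 windows with 11465 genes, and the SD of the window medians was set against 1000 shuffles. This grouping was chosen after fold changes had been seen. Alternatives to the fit covered the replicate number as a block, the filter, the pseudocount, the threshold, a minimum fold change, the groups in the fit and leaving out each library. After the data had been seen, 4 were added: loci with a coding accession and no small RNA, equalised library medians, weights for library quality, and the authors' deposited q-values. With a library left out, the lone library of its group is assumed to vary like the other groups.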

Results

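RNA-seq profiles were analysed from OVISE cells, an established line of human ovarian clear cell carcinoma. Cells with wild-type SYK (SYK-WT) and cells in which SYK had been knocked out (SYK-KO) were left untreated or exposed to epidermal growth factor (EGF) at 50 ng/ml for 24 h. SYK is a non-receptor tyrosine kinase best known from immune cells, and EGF is the ligand of the receptor tyrosine kinase EGFR. The series asks how SYK activity shapes the transcriptome that depends on EGFR. Each of the 4 groups held 2 libraries. The depth, estimated from the value of a single fragment in genes of low expression, ranged from about 23100000 fragments in SYK-KO EGF replicate 1 to about 27200000 in SYK-WT replicate 1 and SYK-KO replicate 2. Of 27757 loci in the deposited table, 12112 reached 1 FPKM in at least 2 libraries and were tested. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Nor do the labels say how many SYK-KO clones entered the libraries, or whether the SYK-WT cells were a clone or the parental culture, so each SYK-KO comparison sets these cells against the SYK-WT cells. Some genes are listed at loci that also hold other entries, so their values are less certain. The entries include antisense transcripts for EGFR, CD68, FOXJ1, HSD11B1, ITGA5, KCNIP1, SREBF1, TMEM132D-AS1 and VIM, and only small RNAs for AMOTL2, BUB1, CDH1, LAPTM5 and WNT9A. They are other genes or transcripts for ARG2, EPHX1, ERBB2, FGD3, FLG, FOXM1, KRT8, MMP1, PLAU, PLK3 and TYMS. TXNIP lies at a locus that spans chromosome 1 from 144146811 to 146467744 (hg19) and holds many other genes.

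The libraries separated first by genotype and then by EGF. The first principal component held 59.6% of the variance and parted SYK-KO from SYK-WT libraries, and the second held 28.3% and parted treated from untreated ones. The SYK-WT pair lay furthest apart: the median absolute difference between its replicates was 0.149 on the log2 scale, against 0.0608 for SYK-KO, 0.0652 for SYK-WT EGF and 0.0771 for SYK-KO EGF. The third component, with 5.97% of the variance, placed SYK-WT replicate 1 at 11.61 and replicate 2 at -15.02.

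**Figure D1:**
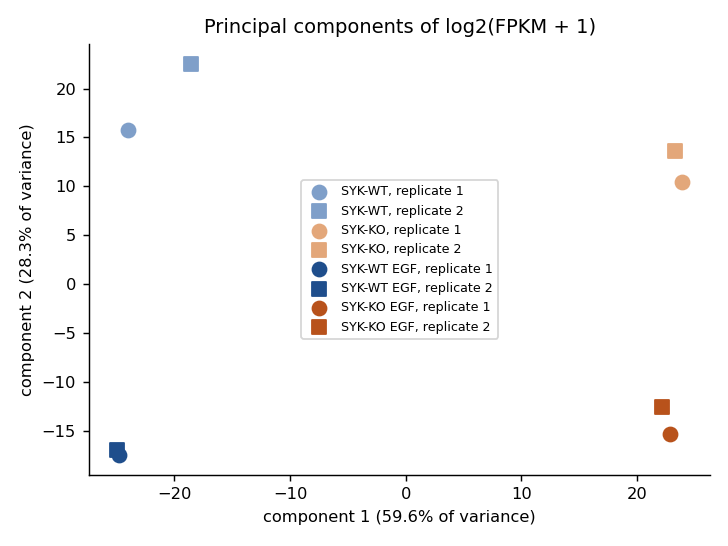
Scores of the 8 libraries on the first 2 principal components of log2(FPKM + 1), with the share of variance on each axis; colours mark the groups and shapes the replicates. Genotype separates along component 1 (59.6%) and EGF along component 2 (28.3%), and the SYK-WT replicates lie at 15.76 and 22.56 on component 2.

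SYK itself (chromosome 9, 93563962 to 93660842, hg19) was present in every library. SYK-WT cells held 4.91 and 5.30 FPKM and SYK-KO cells 3.11 and 3.43 FPKM, and after EGF the values were 3.88 and 3.62 FPKM in SYK-WT and 2.80 and 3.16 FPKM in SYK-KO cells. The transcript was lower in untreated SYK-KO cells by a log2 fold change of -0.52 ± 0.086 (SE, n = 2 libraries per group; limma, Benjamini-Hochberg adjusted p = 0.00289). With EGF the difference was -0.26 ± 0.086 (limma adjusted p = 0.0436), and this call ended when any of the SYK-KO or EGF-treated libraries was left out (adjusted p from 0.0621 to 0.215), with equalised library medians (0.0709) and with no filter on low values (0.0833). In the authors' deposited table SYK had q = 0.2 in this comparison. EGF lowered SYK in SYK-WT cells by a log2 fold change of -0.36 ± 0.086 (limma adjusted p = 0.0191), a call that ended without SYK-WT EGF replicate 1 (0.0722) or 2 (0.121) with only the 2 groups in the fit (0.073) and with library quality weights (0.0737). The 2 guide sequences given in the labels matched the coding part of exon 2 of SYK, on chromosome 9 of GRCh38 at 90844042 to 90844061 on the opposite strand and at 90844080 to 90844099 on the strand of SYK, each beside an NGG motif. Nicks in exon 2 need not remove the transcript, so its level does not check the knockout, which the labels say was checked by immunoblot.

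The first comparison asks which transcripts EGF changed in SYK-WT cells. THBD, encoding the thrombin receptor thrombomodulin, rose from 5.81 ± 0.719 to 73.9 ± 0.554 FPKM (SD, n = 2), a log2 fold change of 3.46 ± 0.092 (SE). PLAT, which encodes tissue plasminogen activator, rose from 2.08 ± 0.119 to 17.4 ± 0.291 FPKM, and MMP1, the interstitial collagenase, from 0.308 ± 0.0509 to 5.14 ± 0.858 FPKM. Rises also passed for the protease inhibitor PI3 (2.58), the neuropeptide precursor VGF (2.21) and the neuronal pentraxin NPTX1 (2.34, but 1.54 without SYK-WT replicate 2 and 3.14 without replicate 1). The cortisone reductase HSD11B1 rose by 2.21, but its locus also holds G0S2 and an antisense transcript, so the value is uncertain. FAM25A rose by 2.70, but its family holds near-identical copies and the value is uncertain. Among the largest falls were the immune checkpoint ligand VTCN1, from 56.2 ± 11.9 to 13.5 ± 2.63 FPKM, the growth factor FGF18 (-1.88), the corepressor RCOR2 (-1.86), the adrenergic receptor ADRA2A (-1.79), the homeobox gene DLX3 (-1.75), the matrix protein CILP (-1.64) and filaggrin, FLG (-1.58). FOXJ1, a regulator of motile cilia, fell by 1.99 on the log2 scale at a locus that also holds an antisense transcript. Fold changes are on the scale of log2(FPKM + 1), which understates the change of low genes. EGFR did not pass (0.38 ± 0.155, limma adjusted p = 0.108), nor did ERBB2 (-0.35, adjusted p = 0.065) or ERBB3 (-0.05, adjusted p = 0.619).

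Gene lists fixed before the data were examined describe the same response by function. Of 12 measured genes of matrix proteases and invasion, 9 rose and 0 fell, and 9 rose and 2 fell when adjusted over the list alone. The urokinase receptor PLAUR (1.76) and urokinase, PLAU (1.82), were among the risers. The list passed against the other genes (camera, Benjamini-Hochberg adjusted p = 4.80e-05; adjusted p = 0.27 with an estimated correlation). Of 11 chemokines, cytokines and NF-kappaB targets, 7 rose, including CXCL8 (2.03), CXCL2 (1.09) and CXCL3 (1.04), and 10 rose when adjusted over the list alone (camera adjusted p = 4.04e-04; adjusted p = 0.502 with an estimated correlation). The median of this list, 0.625, was 0.337 without SYK-WT replicate 2 and 0.898 without replicate 1. Relative to the mean of all libraries, the list mean was -0.709 in SYK-WT replicate 2 and -0.289 in replicate 1, and 0.258 and 0.189 in SYK-WT EGF replicates 1 and 2. Cell cycle genes moved the other way: 17 of 25 fell and 0 rose, and 24 fell when adjusted over the list alone. Among them were the nucleotide reductase subunit RRM2 (-0.75), the topoisomerase TOP2A (-0.53) and the proliferation marker MKI67 (-0.51), with a list median of -0.41 (camera adjusted p = 1.84e-08; adjusted p = 0.502 with an estimated correlation). Of 9 fatty acid synthesis genes 4 fell, 5 when adjusted over the list alone, with the desaturase SCD at -0.48 and the regulator SREBF1 at -0.60 (camera adjusted p = 0.00735; adjusted p = 0.606 with an estimated correlation), and a list median of -0.265 that was -0.137 without SYK-WT replicate 2 and -0.398 without replicate 1.

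Other lists did not pass camera in SYK-WT cells although single members did. With fry, FOXO targets and haematopoietic markers passed (fry adjusted p = 7.15e-04 for each), as did NRF2 targets (0.007). The ERK, ERBB and mesenchymal lists (0.0132 for each) and the epithelial list (0.0398) also passed fry. Among 19 genes of ERK feedback and early response, 6 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.225), with the phosphatase DUSP5 at 1.32 and the feedback inhibitor SPRY1 at -0.97. Of 10 ERBB ligands and receptors, 4 rose and 2 fell (5 and 4 adjusted over the list alone; 0.536), including the ligand HBEGF (1.54) and the EGFR inhibitor ERRFI1 (0.85). Further lists gave 7 risers and 1 faller of 10 NRF2 targets (7 and 2 over the list alone; 0.0616), with the heme oxygenase HMOX1 going from 15.2 ± 1.38 to 38.8 ± 1.01 FPKM, and 2 and 5 of 11 FOXO targets (2 and 5; 0.201), with TXNIP at -1.12. Glycolysis and hypoxia genes gave 4 risers and 0 fallers of 18 (4 and 0; 0.146), with hexokinase HK2 at 0.76, and mesenchymal genes 4 and 1 of 9 (4 and 2; 0.225), with the integrin ITGA5 at 1.51. Epithelial genes gave 5 and 2 of 15 (7 and 2; 0.195), with the keratin KRT8 (1.05), which has many pseudogene copies and is uncertain. For YAP and TEAD targets the counts were 3 and 2 of 10 (3 and 2; 0.963), with AMOTL2 at -0.78, and for the SYK pathway 1 and 3 of 12 (1 and 3; 0.504), with the ubiquitin ligase CBLB at -0.73. Of the 2 measured haematopoietic markers, CD68 rose by 1.35 and LAPTM5 was at 0.19 (limma adjusted p = 0.148; 1 riser, likewise over the list alone; camera adjusted p = 0.0616). Unfolded protein and ATF4 targets gave 6 risers and 4 fallers of 14 (7 and 4 over the list alone; 0.536), p53 targets 4 and 4 of 15 (4 and 4; 0.963), interferon-response genes 1 and 2 of 17 (1 and 2; 0.628) and cholesterol synthesis genes 2 and 3 of 15 (3 and 5; 0.504). Genes high in ovarian clear cell carcinoma gave 1 and 1 of 8 (2 and 1; 0.884) and mesothelial markers 1 and 2 of 4 (2 and 2; 0.888).

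Across all genes, EGF changed 3238 of 12112 in SYK-WT cells, 1777 up and 1461 down (limma, Benjamini-Hochberg threshold 0.05), and 216 of them by at least 1 on the log2 scale. With library medians equalised, the split turned to 1419 up and 1859 down, so the share of rises moved from 54.9% to 43.3%. The count moved to 5108 without SYK-WT replicate 1, to 1255 without SYK-WT EGF replicate 1 and to 1285 without SYK-WT EGF replicate 2, and to 1254 when only the 2 groups entered the fit. In the authors' deposited table, 1843 of the tested loci had q under 0.05, 904 up and 939 down, and 1673 of them were called here in the same direction.

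The second comparison asks what EGF did in SYK-KO cells. MMP1 rose from 3.03 ± 0.138 to 56.3 ± 10.3 FPKM (SD, n = 2), a log2 fold change of 3.82 ± 0.137 (SE), and THBD from 5.77 ± 0.536 to 49.5 ± 2.33 FPKM. HMOX1 reached 147 ± 15.2 FPKM from 42.8 ± 1.98, and the mitochondrial cyclophilin PPIF 172 ± 2.21 FPKM from 49.2 ± 0.824. Further rises were those of the ligand WNT9A (2.23), the integrin ITGA6 (1.73), HBEGF (1.66) and PI3 (1.66). ADRA2A fell from 6.78 ± 1.01 to 1.56 ± 0.00867 FPKM, and the stress response gene NUPR1 from 411 ± 13.0 to 175 ± 4.08 FPKM. KCNIP1, a potassium channel partner (-1.36), the actin-severing protein SCIN (-1.24), the muscle ankyrin repeat gene ANKRD2 (-1.24), the exchange factor FGD3 (-1.16), the non-coding RNA CERNA2 (-1.15) and FOXJ1 (-1.48) also fell. The calls of some ended with a library left out: NUPR1 without SYK-KO EGF replicate 1 (limma adjusted p = 0.0568), CERNA2 without SYK-KO replicate 2 (0.0634), and FOXJ1 without SYK-KO replicate 2 (0.069) or SYK-KO EGF replicate 1 (0.0687).

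By list, 8 of 12 matrix protease and invasion genes rose and 0 fell (9 and 2 adjusted over the list alone), among them PLAUR (1.42) (camera adjusted p = 3.01e-06; adjusted p = 0.182 with an estimated correlation). Of 11 NF-kappaB and cytokine genes 7 rose, 10 when adjusted over the list alone, including CXCL2 (1.17) and CXCL5 (0.73) (camera adjusted p = 4.68e-07; adjusted p = 0.311 with an estimated correlation). Of 19 ERK genes 7 rose and 1 fell, and 10 and 1 when adjusted over the list alone, with DUSP5 at 1.18, SPRY2 at 0.53 and a list median of 0.258 that was 0.171 without SYK-KO EGF replicate 2 (camera adjusted p = 0.00441; adjusted p = 0.311 with an estimated correlation). NRF2 targets gave 4 risers and 0 fallers of 10 (4 and 0 adjusted over the list alone; camera adjusted p = 0.00441; adjusted p = 0.311 with an estimated correlation). Mesenchymal genes gave 2 and 0 of 9 (3 and 0 over the list alone), with ITGA5 at 1.43 (camera adjusted p = 0.00466; adjusted p = 0.311 with an estimated correlation). Both lipid lists were lower. Fatty acid synthesis genes gave 4 fallers of 9 (7 over the list alone), with SCD at -0.57 (camera adjusted p = 2.46e-04; adjusted p = 0.317 with an estimated correlation), and cholesterol synthesis genes 4 of 15 (5 over the list alone), with DHCR7 at -0.51 (camera adjusted p = 0.00466; adjusted p = 0.318 with an estimated correlation). Glycolysis and hypoxia genes gave 5 risers of 18 (6 over the list alone; camera adjusted p = 0.0269; adjusted p = 0.564 with an estimated correlation), a call that ended without SYK-KO EGF replicate 2 (adjusted p = 0.32). Their median was 0.0693, and 0.154 or 0.0391 without SYK-KO EGF replicate 1 or 2, and the list did not pass fry (fry adjusted p = 0.163). Both measured haematopoietic markers rose, CD68 by 0.92 and LAPTM5 by 0.76 (2 of 2, likewise adjusted over the list alone; camera adjusted p = 0.00171; adjusted p = 0.261 with an estimated correlation). Of 25 cell cycle genes 1, the cyclin CCNE1, rose (0.59) and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.0817).

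EGF changed 1429 genes in SYK-KO cells, 808 up and 621 down (limma, Benjamini-Hochberg threshold 0.05), and 708 up and 719 down with library medians equalised. Leaving out a library moved this count to 2982 or 2984 without SYK-WT replicate 1 or 2, to 439 or 319 without SYK-KO replicate 1 or 2, and to 382 or 452 without SYK-KO EGF replicate 1 or 2. With only the 2 groups of each comparison in the fit, EGF changed 2646 genes in SYK-KO and 1254 in SYK-WT cells, which reverses the order of the counts, as did library quality weights, an alternative chosen after the data were seen, with 3024 and 1877. No comparison of these groups by the authors was analysed here.

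The responses of the 2 genotypes pointed the same way at most genes. Of the genes that passed in both, 717 rose in both and 494 fell in both, where independent lists would share 119 and 74.9, and 2 moved in opposite directions. The Spearman correlation of the log2 fold changes across genes, which are not independent replicates, was 0.738 and the Pearson correlation 0.296, and 95.6% of the genes called in SYK-WT cells had the same sign in SYK-KO cells. Both sets of calls use the same variance estimate per gene and are not independent. The number shared in direction was 405 and 292 without SYK-KO replicate 1 and 2, 654 and 663 without SYK-WT EGF replicate 1 and 2, and 343 and 417 without SYK-KO EGF replicate 1 and 2. It was 2138 without SYK-WT replicate 1 and 1961 without SYK-WT replicate 2.

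**Figure D2:**
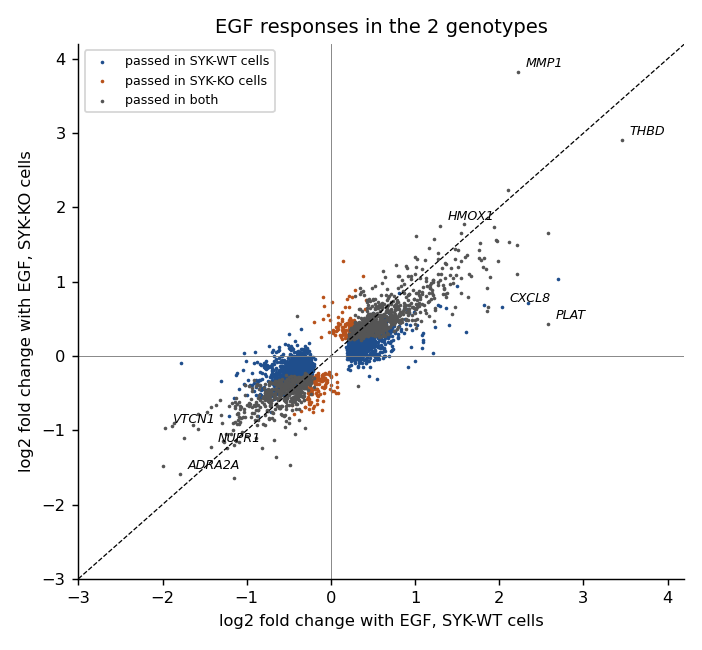
Log2 fold change with EGF in SYK-WT cells (horizontal) and in SYK-KO cells (vertical) for the 3416 loci past the threshold in either, without loci that hold a small RNA; colours show where a locus passed and the dashed line marks equal change. MMP1 lies above the line (2.23 and 3.82) and PLAT far below it (2.58 and 0.43). The 1 added before the log lowers the SYK-WT value of MMP1, whose untreated mean was 0.308 FPKM there and 3.03 FPKM in SYK-KO cells. Its place above the line thus does not show a stronger response in SYK-KO cells.

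The difference between the EGF responses was tested directly. PLAT was the 1 gene that passed: its log2 fold change was 2.58 in SYK-WT cells and 0.43 ± 0.092 in SYK-KO cells (limma adjusted p = 0.0233), from 3.65 ± 0.324 to 5.26 ± 0.603 FPKM. The call in SYK-KO cells ended without SYK-KO replicate 1 (0.0707) or 2 (0.184), SYK-WT EGF replicate 1 (0.0534) or 2 (0.0536) or SYK-KO EGF replicate 1 (0.153), and with no filter on low values (0.0583). The difference was -2.15 ± 0.13 on the log2 scale (SE; limma, Benjamini-Hochberg adjusted p = 0.00259), and it missed the threshold without SYK-WT EGF replicate 1 (adjusted p = 0.0525). For MMP1 the difference was 1.59 ± 0.194 and did not pass (limma adjusted p = 0.0694). MMP1 went from 0.308 to 5.14 FPKM in SYK-WT cells and from 3.03 to 56.3 FPKM in SYK-KO cells. The 1 added before the log lowers its SYK-WT fold change most, so 1.59 does not show a stronger response in SYK-KO cells. At an unadjusted p under 0.05 there were 1070 genes, where 606 are expected with no effect. The count past the adjusted threshold was 867 without SYK-WT replicate 1, 52 without SYK-WT replicate 2 and 0 without SYK-WT EGF replicate 1. It was 3 without SYK-KO replicate 2, and 2 without SYK-WT EGF replicate 2, SYK-KO EGF replicate 1 or SYK-KO EGF replicate 2. By list, the cell cycle genes differed by camera at the preset correlation, with a median difference of 0.31 (0 of 25 members called, 3 adjusted over the list alone; camera adjusted p = 2.12e-13; adjusted p = 0.868 with an estimated correlation). The list did not pass fry (fry adjusted p = 0.63). On average over the list, SYK-WT cells lay at -0.0125 and 0.18 untreated and at -0.269 and -0.362 with EGF, and SYK-KO cells at 0.15 and 0.16 untreated and at 0.0731 and 0.081 with EGF, relative to the mean of all libraries.

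**Figure D3:**
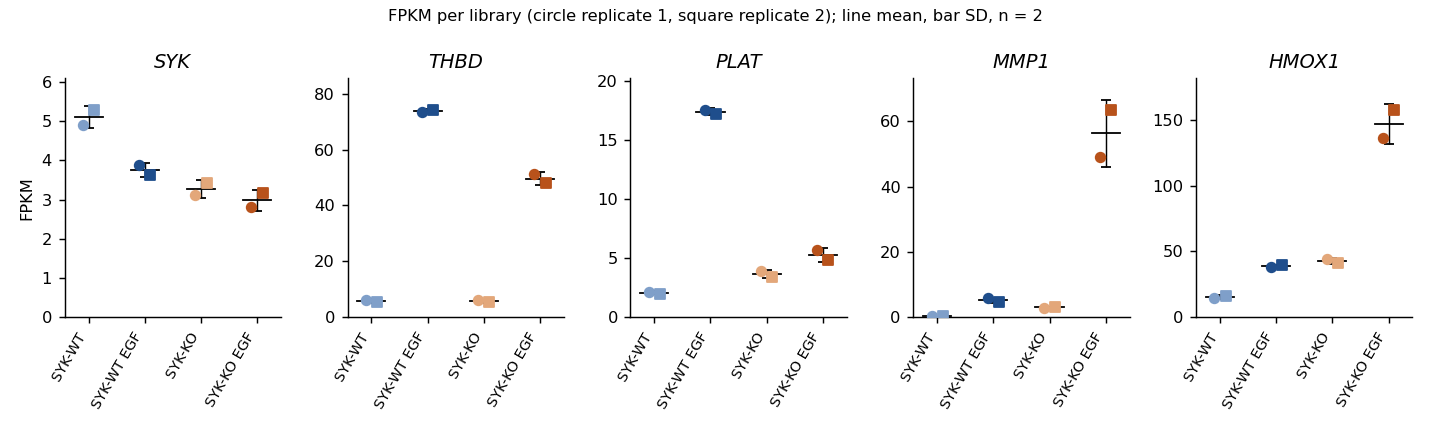
FPKM of SYK, THBD, PLAT, MMP1 and HMOX1 in each library, with the group mean as a line and the SD as a bar (n = 2); the vertical axes start at 0 and differ between panels. With EGF, PLAT reached 17.4 FPKM in SYK-WT and 5.26 FPKM in SYK-KO cells, and MMP1 5.14 and 56.3 FPKM.

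The third comparison asks how untreated SYK-KO cells differed from untreated SYK-WT cells. EIF4EBP1, which encodes the translation repressor 4E-BP1 (chromosome 8, 37888020 to 37917883, hg19), was at 49.0 ± 2.57 FPKM in SYK-KO and 0.387 ± 0.203 FPKM in SYK-WT cells (SD, n = 2), a log2 fold change of 5.18 ± 0.121 (SE; limma, Benjamini-Hochberg adjusted p = 7.35e-07). The chemokine CXCL5 stood at 20.1 ± 0.207 FPKM in the SYK-KO libraries and was listed at 0 in both SYK-WT libraries. EPHX1, the microsomal epoxide hydrolase, was at 95.1 ± 1.31 against 6.69 ± 0.811 FPKM, and NUPR1 at 411 ± 13.0 against 57.8 ± 19.3 FPKM. The embryonic globin HBE1 (3.21), the collagen chaperone FKBP10 (2.99), THSD1 (2.77) and the homeobox gene DLX5 (2.71) were also higher. Lower in SYK-KO cells were the aldolase ALDOC, at 5.20 ± 0.298 against 100 ± 22.5 FPKM, the lactate receptor HCAR1 (-3.90), YPEL3 (-3.67), the glutamate transporter SLC1A6 (-3.51), the calcium-binding protein S100A9 (-3.24), the mucin MUC5AC (-3.02), the receptor FGFR3 (-2.91) and mesothelin, MSLN (-2.73). In the authors' deposited table HCAR1 had q = 0.101. ERBB2 (-0.56, limma adjusted p = 0.00795) and ERBB3 (-0.43, adjusted p = 0.0029) were lower, the former not without SYK-KO replicate 1 (adjusted p = 0.0626), while EGFR did not pass (0.05 ± 0.155, adjusted p = 0.807).

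Of 17 interferon-response genes, 13 were higher and 1 lower in SYK-KO cells, both over all genes and adjusted over the list alone, with OAS2 at 2.07, IFI27 at 2.37 and MX1 at 1.31 (camera adjusted p = 3.85e-05; adjusted p = 0.516 with an estimated correlation). The list mean differed between the SYK-WT replicates (-0.247 and -0.521). Unfolded protein and ATF4 targets gave 11 higher and 2 lower of 14 (12 and 2 over the list alone), including the serine synthesis enzyme PHGDH (1.22) and the transcription factor ATF3 (0.99) (camera adjusted p = 0.00215; adjusted p = 0.336 with an estimated correlation). Of 15 p53 targets 8 were lower and 0 higher (9 and 0 over the list alone), with the kinase PLK3 at -1.11 and BTG2, which restrains proliferation, at -0.74 (camera adjusted p = 0.00808; adjusted p = 0.336 with an estimated correlation). Matrix protease genes gave 7 higher and 0 lower of 12 (7 and 1 over the list alone), with MMP1 at 1.62 and the integrin ITGA2 at 1.68 (camera adjusted p = 0.0117; adjusted p = 0.336 with an estimated correlation).

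Genes of lists that did not pass camera also changed. Among the lists given here, the clear cell carcinoma list (fry adjusted p = 0.0253) and the mesothelial list (0.007) passed fry. Within the mesenchymal list (3 higher and 3 lower of 9, and 3 and 4 adjusted over the list alone; camera adjusted p = 0.966), vimentin, VIM (1.68), and TWIST1 (1.35) were higher and fibronectin, FN1, was lower (-1.84), and within the epithelial list (3 and 5 of 15, likewise over the list alone; 0.705) the cadherin CDH1 was lower (-1.07). Of 8 genes high in ovarian clear cell carcinoma, 4 were higher and 2 lower (4 and 2 over the list alone; 0.433), with ARG2 at 1.06 (q = 0.0695 in the authors' deposited table) and NAPSA at -1.65. Of 15 cholesterol synthesis genes 3 were higher and 3 lower (likewise over the list alone; 0.966). Of 4 measured mesothelial markers 1 was higher and 2 lower (1 and 2 over the list alone; 0.899), with MSLN the lowest, and of 2 measured haematopoietic markers LAPTM5 was lower (-0.49) and CD68 higher (0.35, a call lost without SYK-KO replicate 1 at an adjusted p of 0.0606, and q = 0.333 in the authors' deposited table) (camera adjusted p = 0.966). The fibroblast and endothelial marker lists had 0 measured members, with no value above 0.368 and 0.336 FPKM in any library.

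In all, 4902 genes differed, 2461 higher and 2441 lower in SYK-KO cells (limma, Benjamini-Hochberg threshold 0.05), and 363 by at least 1 on the log2 scale. Without SYK-KO replicate 1 or 2 the count was 2460 or 2841, with only the 2 groups in the fit 3007, and 2609 of the tested loci had q under 0.05 in the authors' deposited table, of which 2536 were called here in the same direction. Neighbouring genes shifted together: the median log2 fold change over windows of about 100 genes had an SD of 0.147 across 117 windows, against at most 0.0492 in 1000 shuffles of the genes' places. For EGF in SYK-WT cells the SD was 0.0422, against at most 0.0382 in shuffles. On chromosome 4 from 140211071 to 190884359 (hg19) the median was 0.42 in SYK-KO against SYK-WT cells, and on chromosome 19 it was 0.31 from 10596796 to 15560762 and -0.29 from 49458117 to 54663481. All windows of chromosome X were higher (0.255, 0.286, 0.328 and 0.312), as were those of chromosome 11 from 76156069 to 134246218 (0.304 and 0.318). MMP1, at a locus on chromosome 11 from 102654407 to 102714420, lies in the window at 0.304. Genes of the same shifted window are not separate observations of an effect of the knockout. Windows of chromosome 1 from 134773 to 24863510 were lower (-0.22 and -0.218), and further windows shifted in either direction.

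**Figure D4:**
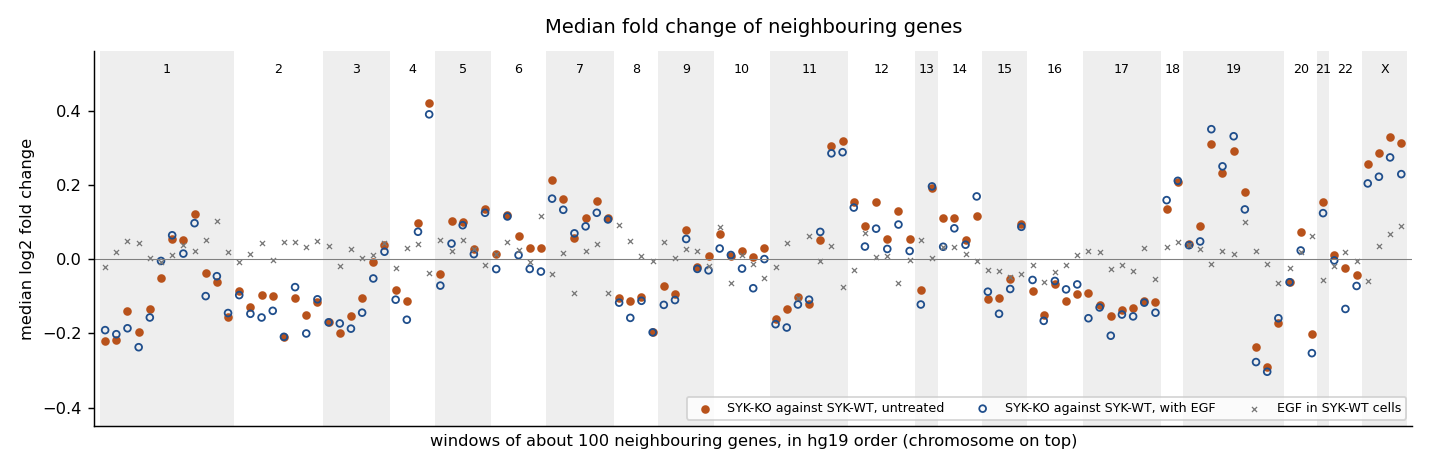
Median log2 fold change of windows of about 100 neighbouring genes in hg19 order, for SYK-KO against SYK-WT cells untreated (filled) and with EGF (open circles) and for EGF in SYK-WT cells (crosses); shading marks chromosomes. The window at the end of chromosome 4 lies at 0.42 untreated and 0.39 with EGF, and at -0.0375 for EGF in SYK-WT cells.

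The fourth comparison asks how the genotypes differed with EGF. CXCL5 was at 34.1 ± 0.122 FPKM in SYK-KO EGF cells, and in SYK-WT EGF cells it was listed at 0 in replicate 1 and at 0.0161 FPKM in replicate 2. EIF4EBP1 (5.08), HBE1 (3.24), MMP1 (3.22), EPHX1 (3.20), FKBP10 (3.11), NUPR1 (3.05) and the adaptor DOK5 (2.58) were higher in SYK-KO cells. ALDOC (-4.31), HCAR1 (-4.06), YPEL3 (-3.91), SLC1A6 (-3.81), MUC5AC (-3.62) and S100A9 (-3.13) were lower. In the authors' deposited table CXCL5 had q = 0.487 and HCAR1 q = 0.172. The kallikrein protease KLK6 was at 48.0 ± 4.86 FPKM against 545 ± 16.2 FPKM in SYK-WT EGF cells (SD, n = 2), a log2 fold change of -3.48 ± 0.119 (SE; limma, Benjamini-Hochberg adjusted p = 2.46e-06), and TMEM132D-AS1, an antisense transcript and uncertain without strand, was at -2.99. ERBB2 (-0.48, limma adjusted p = 0.0142) and ERBB3 (-0.55, adjusted p = 9.01e-04) were lower, the former not without SYK-WT EGF replicate 2 (adjusted p = 0.0892) or SYK-KO EGF replicate 1 (0.0957).

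Cell cycle genes were higher in SYK-KO than in SYK-WT cells with EGF, 18 of 25 against 1 lower (19 and 1 adjusted over the list alone), with FOXM1 at 0.74, TYMS at 0.83 and BUB1 at 0.50 (camera adjusted p = 2.05e-05; adjusted p = 0.832 with an estimated correlation). Interferon-response genes gave 12 higher and 1 lower of 17 (13 and 1 over the list alone; camera adjusted p = 3.06e-05; adjusted p = 0.722 with an estimated correlation), p53 targets 0 higher and 9 lower of 15 (0 and 9 over the list alone; camera adjusted p = 0.00997; adjusted p = 0.55 with an estimated correlation), and unfolded protein and ATF4 targets 10 and 2 of 14 (10 and 2 over the list alone; camera adjusted p = 0.0112; adjusted p = 0.722 with an estimated correlation). Matrix protease genes, which passed camera untreated, did not pass it with EGF, with 5 higher and 3 lower of 12 (6 and 3 over the list alone; camera adjusted p = 0.336). With fry this list passed (fry adjusted p = 0.00744). In all, 5277 genes differed, 2553 higher and 2724 lower (limma, Benjamini-Hochberg threshold 0.05), a split that turned to 2867 higher and 2305 lower with library medians equalised. The count fell to 3078 and 2952 without SYK-WT EGF replicate 1 and 2, and to 3164 and 3372 without SYK-KO EGF replicate 1 and 2, and 2911 tested loci had q under 0.05 in the authors' deposited table, 1581 higher and 1330 lower.

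**Figure D5:**
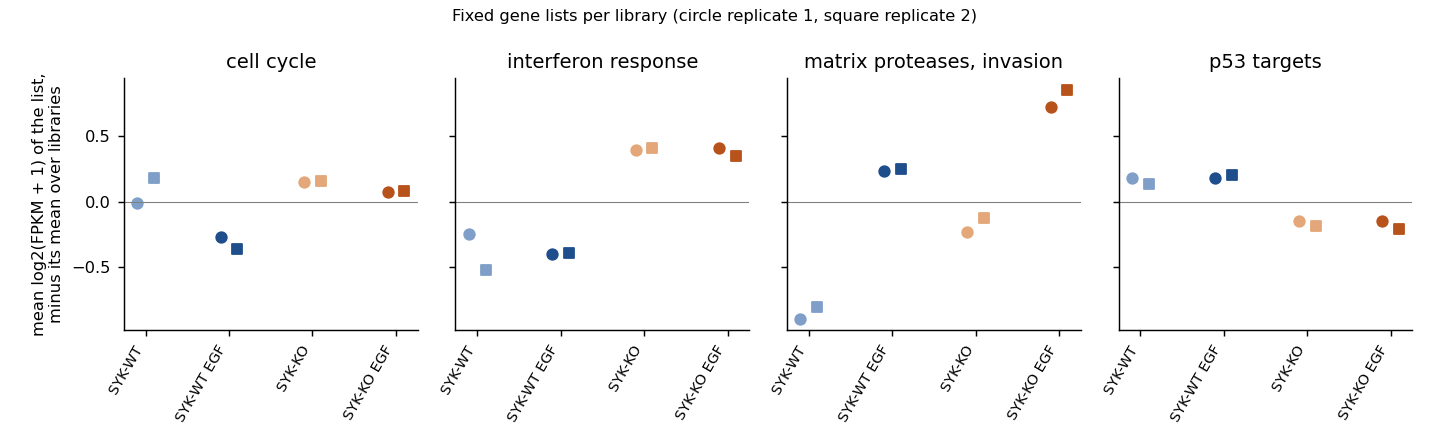
Mean log2(FPKM + 1) of the measured members of 4 fixed lists in each library, minus the list's mean over all libraries; colours mark groups, circles replicate 1 and squares replicate 2. Cell cycle genes lie lowest in the SYK-WT EGF libraries (-0.269 and -0.362).

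The genotype differences of single genes without and with EGF were also compared. Of the genes that passed in both, 1874 were higher and 1880 lower in SYK-KO cells in both, where independent lists would share 519 and 549, and 7 pointed in opposite directions. The Spearman correlation of the fold changes across genes was 0.851 and the Pearson correlation 0.577. The number shared in direction fell to 2165 and 2327 without SYK-KO replicate 1 and 2, to 2479 and 2357 without SYK-WT EGF replicate 1 and 2, and to 2454 without SYK-KO EGF replicate 1.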

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

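Of the alternatives behind the range given for PLAT, those with coding loci alone, equalised library medians and quality weights were chosen only after the data were seen, and the genes with opposite responses were found by screening the 183 named genes. PLAT stood out because its EGF response differed between the genotypes by -2.15 on the log2 scale in the direct test (limma, adjusted p = 0.00259). The adjusted p ranged from 4.91e-04 with coding loci alone to 0.0525 without SYK-WT EGF replicate 1. The cell cycle list stood out with a median difference of 0.31 (camera adjusted p = 2.12e-13; adjusted p = 0.868 with an estimated correlation), but did not pass fry (fry adjusted p = 0.63).

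Among 183 named genes, 6 had EGF responses that pointed in opposite directions in every library of the genotypes. Genes that passed the test of the difference (limma, Benjamini-Hochberg) were left out of this screen, so none of the 6 could have passed. The difference was 0.296 for BUB1 (adjusted p = 0.454), -0.371 for CRIM1 (0.43), 0.306 for DOK5 (0.537), -0.324 for ISG15 (0.435), -0.254 for MYC (0.465) and 0.552 for SNAI1 (0.313). Within a genotype, only the SYK-WT responses of CRIM1 (limma adjusted p = 0.0318) and SNAI1 (0.0105) passed. With 2 libraries per group, genes that do not respond can also separate in this way, so the screen does not show opposite responses.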

How the results depend on the processing

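The alternatives with coding loci alone, equalised library medians, library quality weights and the authors' q-values were chosen only after the data were seen. Of 7483 values of 381 results on named genes, 6828 counted as the same, 569 lost a call, 86 gained one and 0 reversed. A change of direction counted as reversed only for a called result, and as the same for an uncalled one. Of 352 values of 22 list results (a list in a contrast), 329 kept their direction and side of the threshold. The other 23 lost the call, 22 of them with an estimated correlation, under which 0 lists passed. With only the compared groups in the fit, counts were 1254 (EGF in SYK-WT), 2646 (EGF in SYK-KO) and 3007 (SYK-KO untreated). At an adjusted p under 0.01 they were 1327, 495, 2684 and 2947 for SYK-KO with EGF, with 416 and 1954 genes shared between the EGF responses and between the SYK-KO effects. With a log2 fold change of at least 1 as well, they were 216, 95, 363 and 411, with 73 and 264 shared, and SYK at -0.516 no longer counted, by construction. Quality weights gave 1877 and 3024 for EGF in SYK-WT and SYK-KO, which reverses their order as the fit of the compared groups did, and the authors' q gave 1843 for EGF in SYK-WT, 2609 and 2911 for the SYK-KO effects and 1886 shared. Without a filter, 797 genes were shared between the EGF responses. The difference of the responses had 2 genes without a filter, 16 with pseudocount 5, 9 with coding loci and 2 with quality weights. Of 340 called values of named genes, pseudocount 5 made 95 smaller by over 1.5 times and pseudocount 0.1 made 28 larger, with 0 reversed. Apart from stricter thresholds, the cause was not tested. Leaving out a library gave 1255 to 5108 for EGF in SYK-WT and 319 to 2984 for EGF in SYK-KO. It gave 2460 to 5935 for SYK-KO untreated, 2952 to 6835 with EGF and 0 to 867 for the difference. It also gave 292 to 2138 and 2165 to 4928 shared genes, and -0.571 to -0.461 for SYK. Over all contrasts, 21 to 30 list results passed when a library was left out. With the replicate number as a block, counts were 3624, 1653, 5261, 5688 and 1. Over all contrasts 23 list results passed, against 22 in the main fit. Deviations of same-numbered libraries correlated at 0.18 to 0.3 among SYK-WT, SYK-KO and SYK-KO EGF, and at -0.42 to -0.18 between each of these and SYK-WT EGF. The deviations thus share a structure, but not one that follows the numbers in every group, and the labels tie no number to a shared batch, so the numbers were not taken as pairs. The count-based alternatives were not run because the values are FPKM, nor was a new adjustment of the authors' p-values, since the authors' comparisons were not the main result. Depth as estimated differed little between libraries (about 23100000 to 27200000 fragments), an estimate that holds only if FPKM were scaled by each library's fragments. Depth limits genes near 1 FPKM.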

Other observations

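Gene families, KLK8 and KLK10, the windows near 0, the mixing share, the EGF-like state, depth, the clone question, the own-spread count and the quality weights were tests chosen only after results were seen. Of 199 families grouped by symbol, IFI genes, many of them induced by interferon, were higher in untreated SYK-KO cells for 7 of 8 members and lower for 0 (camera adjusted p = 0.00162, and 0.949 with an estimated correlation), with IFI6 at 1.32 and IFI16 at 1.18. IFI16 was low, at 1.77 against 0.223 FPKM, and moved to 2.53 with pseudocount 0.1 and to 0.373 with pseudocount 5. CYP genes, which encode cytochrome P450 enzymes, were higher for 8 of 12 (camera adjusted p = 0.00178; adjusted p = 0.949 with an estimated correlation). With EGF in SYK-WT cells, 8 of 14 PSMD genes, which encode proteasome subunits, rose and 0 fell (camera adjusted p = 0.0204; adjusted p = 0.992 with an estimated correlation). The family median was 0.262, and untreated SYK-WT replicates 1 and 2 differed, at 66.6 and 52.5 FPKM for PSMD14 and 39.1 and 35.9 FPKM for PSMD11. The rise of PSMD14, 0.612, was 0.443 without SYK-WT replicate 2 and 0.78 without replicate 1. Of 18 IFT genes, which serve transport in cilia, 7 fell with EGF in SYK-WT cells and 3 in SYK-KO cells (camera adjusted p = 0.0204 and 0.00411; adjusted p = 0.992 and 0.942 with an estimated correlation). The genes named here were picked after their values were seen. The kallikrein genes KLK8 (-1.50) and KLK10 (-1.62) were lower in SYK-KO cells with EGF (limma adjusted p = 9.36e-06 and 6.30e-05). Both were also lower untreated, at -0.93 and -0.452 (limma adjusted p = 8.17e-05 and 0.015). The difference of their EGF responses did not pass (limma adjusted p = 0.186 and 0.106). Whether a shift of their chromosome window has a part in their lower values was not tested. KLK10, at 0.561 FPKM in SYK-KO EGF cells, moved to -2.55 with pseudocount 0.1 and to -0.661 with pseudocount 5.

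SYK-KO and SYK-WT cells differed at 4902 genes untreated and 5277 with EGF. Shifts of whole chromosome segments may be part of this, since window medians had an SD of 0.147 against at most 0.0492 in shuffles, although exceeding the shuffles is not specific to segments: EGF in SYK-WT cells gave 0.0422 against at most 0.0382. Windows whose median lay within 0.05 of 0 still had 34.6% of genes called, against 42.7% in the other windows. This argues against shifts of whole windows as the whole cause. It cannot speak to shorter segments, or to effects of a segment on genes elsewhere, and this test was written after the first. In the first, 64.4% of calls stayed after window medians were removed, between the bounds of 50 and 80 percent set beforehand, so it alone did not decide, and the rule of the verdict was changed after that value was seen. Differences between a clone and the SYK-WT cells, which the labels call neither parental nor a clone, cannot be told apart from SYK loss. The protocols describe isolation of single-cell clones, but the sample labels tie no library to a clone, so changes cannot be compared between clones.

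The SYK-WT replicates differed more than those of any other group. Depth as estimated here is argued against by the SYK-WT EGF pair, which had the same estimated relative depths and a median difference of 0.0652 against 0.149. The estimate may reflect the scaling of the libraries and not their depth. GC content and transcript length as the whole cause are argued against by the 0.131 left after their trends were removed, against at most 0.0654 in the other groups, although the difference followed GC content at a Spearman correlation across genes of -0.494, where the other pairs lay between -0.25 and 0.124. Material of EGF-treated cells in replicate 1 is argued against by a median share of 0.00469 over 51 genes, although AREG and PTGS2 would need 0.403 and 0.63. A partly EGF-like state of that culture could not be decided, with a Spearman correlation across genes of 0.111 where other pairs reached 0.245.

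In the main fit, EGF changed fewer genes, and by less, in SYK-KO than in SYK-WT cells, a description widened to the sizes after its tests had run. The order of the counts depended on the fit. For the sizes, picking genes by their SYK-WT response is argued against by slopes of the SYK-KO on the SYK-WT response of 0.721 to 0.776 (median 0.742) over choices of pairs, and by slopes of the SYK-WT on the SYK-KO response of 1.13 to 1.46 (median 1.19), which lie above 1 but show a smaller gap. The pairs within a choice share no library, but all choices use the same libraries. The ranges are thus not an uncertainty of the slopes. For the counts, the spread shared by all groups is a candidate explanation, since with its own spread each genotype gave 2646 genes in SYK-KO and 1254 in SYK-WT cells, and library quality weights also reversed the order, with 3024 and 1877. The loss of SYK stays open as an untested explanation.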
